A study of Mus musculus with 6 samples.

How the data were processed

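Single-cell RNA-seq of adult ICR mouse testis (ICR is an outbred stock) was analysed in 6 libraries, 3 from control mice and 3 from mice exposed to cigarette smoke. Per the labels' protocols, mice were bought at 6 weeks of age, adapted for 1 week and exposed for 12 weeks, 30 minutes per day, to the smoke of 15 cigarettes per session. Nicotine was 1.1 mg and tar 11 mg per cigarette, the smoke particle concentration was 3.47 mg/m3, and control mice were placed in a chamber without smoke. The age label of 8 weeks differs from this schedule. Per the labels' protocols the left testis was taken, dead cells were depleted, and libraries were made with the 10x Genomics 3′ chemistry, in which each unique molecular identifier (UMI) marks a captured RNA molecule. The labels give 7 mice per group and do not say which mouse or mice each of the 3 libraries per group came from, so p-values measure only the spread between these libraries. The labels give no batch or litter.

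The deposited values are raw UMI counts per gene and barcode for 30905 genes, with barcodes already filtered to called cells. Per the file headers the count matrices were written by Cell Ranger 3.1.0, whereas the submitters' processing notes name Cell Ranger 7.1.0, CASAVA 1.8 and genome build mm10, and neither source settles which version made the deposited counts. In the files 62 symbols are shared by 127 genes. These were kept apart by gene identifier. Gene positions come from the GENCODE release M21 annotation of GRCm38, which is mm10. Per-gene UMI counts can mix a gene with a near-identical copy, so ribosomal protein genes, predicted genes (Gm and Rik symbols) and gene families are uncertain to that extent, as are antisense genes, since the use of strand in counting is not given in the sources used here.

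The libraries held 8598, 8844 and 8703 deposited barcodes in controls 1 to 3 and 8839, 9293 and 9976 in smoking libraries 1 to 3. Barcodes with under 500 UMIs, under 300 genes or over 20% mitochondrial UMIs were removed. No deposited barcode had fewer than 1554 UMIs or 636 genes, so only the mitochondrial limit took effect, removing 2459 of 54253 barcodes. Doublets were scored per library against simulated pairs of barcodes with 50 neighbours, and the highest scores were removed at a rate of 0.8% per 1000 barcodes (3935 barcodes, some of which also failed the filter). This left 47958 barcodes.

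Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes without mitochondrial and ribosomal genes gave 30 principal components. All deposited barcodes were clustered by Leiden at resolution 1 on a shared-neighbour graph of 20 neighbours, and removed barcodes were left out afterwards. Clusters were named from fixed marker lists for 15 cell types, called X-like because no deposited annotation was used. A name needed at least 3 markers with a log2 fold of at least 1 over all other barcodes (pseudocount 0.05 per 10000), each seen in at least 20% of the cluster's barcodes. Clusters with markers of 2 types were split at resolution 0.5, and clusters whose leading genes went against the name stayed unnamed. This rule was set after the data were seen: a first rule that used only marker counts had named a cluster of low-UMI barcodes as red blood cells and left most spermatogonia unnamed. It left 61.3% ± 5.73 of barcodes unnamed in controls and 54.4% ± 0.627 in smoking libraries (SD, n = 3). Marker genes define the classes and are not reported as findings between classes.

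Raw counts were summed per class and library, and 8 classes with at least 20 barcodes in every library were tested, as was the sum of all retained barcodes. Smoking was compared with control with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05 within a class). Standard errors of edgeR log2 folds are the absolute fold divided by the square root of the F statistic. The difference of the smoking effect between neighbouring germ cell classes was tested with limma on within-library differences of log2 CPM (prior count 1). Shares of barcodes, ratios of classes and library measures were compared with exact two-sided permutation tests over 20 assignments, which cannot give a p under 0.1. Fixed gene lists with at least 5 measured genes were tested with camera from limma (inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 253 list and class pairs, and with fry. The list of red blood cell transcripts had fewer than 5 measured genes in every class and gave no test.

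Genes are named by a fixed rule. Among genes past the threshold with a mean of at least 10 CPM and no overlap between the groups, it takes the 10 largest rises and 10 largest falls in germ cell classes and in all cells, and 5 and 5 in somatic classes. Where fewer than 3 genes pass, the 5 smallest p-values among genes with a mean of at least 10 CPM are given as values. Up to 4 members per list past the threshold, 8 smoke-response genes and 7 Leydig cell genes are added. Some genes that meet the rule are not reported here. Sample groups, tests, covariates, gene and marker lists, the naming of genes and the first set of alternatives below were fixed before the data were examined.

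Free RNA, which enters every droplet from lysed cells, was estimated per library. Its profile was the summed counts of unnamed barcodes below the 0.25 quantile of UMIs. Its amount per barcode was set from protamine and transition protein UMIs in macrophage-, mesenchymal-, endothelial- and myoid-like barcodes, which should lack them. It came to 1950 ± 49.4 UMIs per barcode in controls and 1866 ± 278 in smoking libraries (SD, n = 3), 65.3% to 78.5% of a library's median barcode. The estimate is rough: for some genes it exceeds the measured count, and such genes are given as 100%.

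The first set of alternatives was DESeq2, limma-voom, upper-quartile scaling, no filter on low counts, thinning to the shallowest library, no filter on barcodes, a stricter filter, doublets kept, Leiden resolution 0.5 and 2, sums reweighted to 1 mix of clusters in every library (stage-matched sums), germ cells as the denominator, and leaving out each library. Alternatives added after the data were seen were barcodes of at least 6000 UMIs, subtraction of the expected free RNA, this together with stage matching, named barcodes as the denominator, and leaving out controls 1 and 2. For shares, the log2 ratio of group means was chosen as the scale of comparison between settings after the shares were known. On that scale 11 of 146 alternative values moved by more than the spread between libraries, against 21 on the scale of percentage points.

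The edgeR test, camera at its fixed correlation and the limma test of differences between classes were run on simulated counts with 200 changed genes. The other tests were not. Simulated genes varied independently, so this run of camera could not show an effect of correlation between genes. In elongating-spermatid-like sums edgeR recovered 24.2% of genes changed 1.5-fold, 66.7% of those changed 2-fold and 98.4% of those changed 4-fold. These were 16, 44 and 63 genes, called together with 12 unchanged genes among 10909 tested. In Leydig-like sums the shares were 3.13%, 6.56% and 76.9% (2, 4 and 50 genes), with 1 unchanged gene called among 6048. In macrophage-like sums they were 19.1%, 63.5% and 100% (12, 40 and 66 genes), with 6 unchanged genes called among 4452. As a share of edgeR calls, unchanged genes exceeded the rate set by the adjusted p threshold in every sum except Leydig- and macrophage-like. For the difference between elongating- and round-spermatid-like sums, limma called 96 of 239 true differences of at least 1 on the log2 scale and 5 of 10597 unchanged genes. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Endothelial- and peritubular-myoid-like sums were left out of the gene tests because some libraries held under 20 of their barcodes.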

Results

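Testis cells of adult ICR mice were profiled by droplet single-cell RNA-seq in 3 libraries from control mice and 3 from mice exposed to cigarette smoke for 12 weeks, to ask how passive smoking affects the testis and spermatogenesis. The deposited barcodes held 40675108, 39607204 and 54915594 UMIs in controls 1 to 3 and 55751481, 65728120 and 78455606 UMIs in smoking libraries 1 to 3. After filtering, 7701, 7992 and 7837 control barcodes and 7711, 8082 and 8635 smoking barcodes were retained. A retained barcode had a median of 2598 ± 99.6 UMIs in controls and 2644 ± 191 in smoking libraries (SD, n = 3, exact permutation p = 0.8), and a median of 1454 ± 32.0 against 1463 ± 68.2 genes (exact p = 0.9). The 5 most abundant genes took 11.2% ± 1.15 of UMIs in controls and 14.2% ± 0.929 in smoking libraries (exact p = 0.1, the smallest that 3 against 3 libraries allow). Barcodes with at least 6000 UMIs made up 11.0% ± 4.97 of controls and 18.0% ± 3.99 of smoking libraries (exact p = 0.3), and the median mitochondrial share was 0.436% ± 0.0234 against 0.276% ± 0.139 (exact p = 0.2).

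No pair of libraries agreed within sampling noise. The chi-square per degree of freedom over genes was 11.32 between controls 1 and 2, but 36.28 and 24.09 between control 3 and these, and 11.11 between control 3 and smoking library 1, the lowest of all pairs. It was 22.58 between control 3 and smoking library 2 and 41.02 between control 3 and smoking library 3. Within the smoking group it ranged from 19.97 to 47.8. For equal relative differences this measure grows with UMI depth, which was highest in the smoking libraries. The correlation of log2 CPM of control 3 was 0.9948 and 0.9954 with controls 1 and 2. It was 0.9965, 0.996 and 0.9938 with smoking libraries 1 to 3. Control 3 was therefore closer in counts to smoking libraries 1 and 2 than to either other control. The mix of cells went with this. Elongating-spermatid-like cells gave 29.5% of retained UMIs in control 3 and 30.2% in smoking library 1, against 16.7% and 12.8% in controls 1 and 2. Barcodes with at least 6000 UMIs made up 16.7% and 15.8%, against 8.54% and 7.67%. A wrong label, a batch, a difference between mice and a difference in the cells captured all stay open for this library, since the labels give no batch and do not tie libraries to mice. It enters every comparison of the groups: in elongating-spermatid-like cells edgeR called 146 genes with it and 2213 without control 3.

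Germ cells at 4 stages of spermatogenesis and 6 somatic classes were found in both groups. Spermatogonia-like cells, the mitotic germ cells that include the stem cells, made up 0.825% ± 0.104 of retained barcodes in controls and 0.568% ± 0.117 in smoking libraries (SD, n = 3), with no overlap between the groups. Their share was 1.65% and 1.22% at Leiden resolution 2 and 2.99% and 1.84% of germ cells alone, with overlap in both (exact p = 0.2). Elongating-spermatid-like cells, in which chromatin is compacted by protamines, made up 4.49% ± 3.0 and 9.92% ± 4.16. Spermatocyte-like cells, which undergo meiosis, made up 8.65% ± 0.861 and 7.32% ± 1.12, and round-spermatid-like cells 14.2% ± 1.77 and 14.1% ± 1.8. Among somatic classes, Sertoli-like cells made up 8.04% ± 1.39 and 10.7% ± 4.57, testosterone-producing Leydig-like cells 0.711% ± 0.210 and 1.08% ± 0.310, and macrophage-like cells 0.821% ± 0.107 and 0.747% ± 0.162. Mesenchymal-like cells made up 0.584% and 0.612%, endothelial-like cells 0.122% and 0.251%, and peritubular-myoid-like cells 0.217% and 0.285%. Unnamed barcodes made up 61.3% ± 5.73 and 54.4% ± 0.627 (exact p = 0.1).

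None of these shares differed past the threshold. The two-sided exact permutation p was 0.1 for spermatogonia-like cells, 0.2 for Leydig- and endothelial-like cells, 0.3 for elongating-spermatid- and spermatocyte-like cells, 0.5 for Sertoli-like cells, 0.6 for macrophage-, mesenchymal- and myoid-like cells and 1.0 for round-spermatid-like cells. Adjusted p-values were 0.55 or higher. On cell numbers edgeR gave log2 folds of −0.54 for spermatogonia-like and 1.15 for elongating-spermatid-like cells, and no class passed (lowest adjusted p = 0.314). The log2 ratio of elongating- to round-spermatid-like cells was −1.85 ± 0.73 in controls and −0.58 ± 0.55 in smoking libraries (exact p = 0.2), that of round-spermatid- to spermatocyte-like cells 0.71 ± 0.27 and 0.95 ± 0.16 (exact p = 0.3), and that of spermatocyte- to spermatogonia-like cells 3.39 ± 0.06 and 3.70 ± 0.32 (exact p = 0.4). Among barcodes with at least 6000 UMIs, Sertoli-like cells lay in the other direction, at 4.94% in controls and 2.96% in smoking libraries (exact p = 0.1). Elongating-spermatid-like cells made up 35.2% and 52.0% of these barcodes and spermatocyte-like cells 12.3% and 7.57%, both without overlap (exact p = 0.1).

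**Figure D1:**
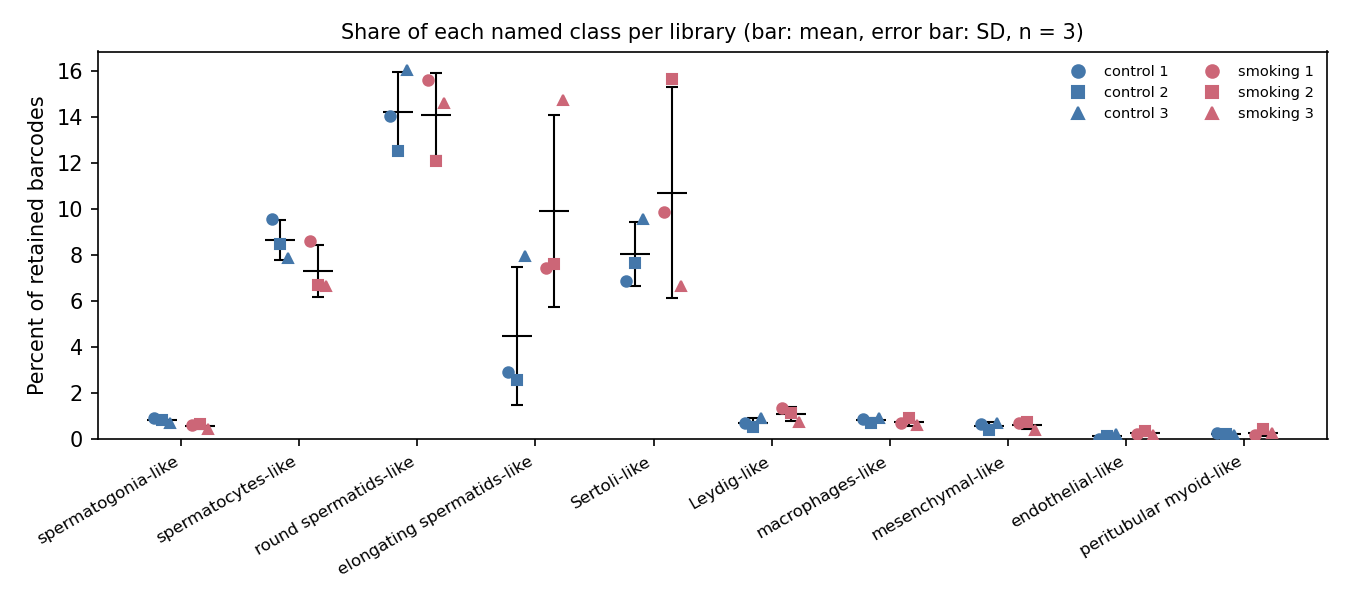
Percent of retained barcodes in each named class (y axis) for 3 control and 3 smoking libraries, with 1 point per library, a bar at the group mean and an error bar of 1 SD (n = 3). Spermatogonia-like cells lie at 0.825% in controls and 0.568% in smoking libraries without overlap, and elongating-spermatid-like cells at 4.49% and 9.92% with overlap.

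Spermatogonia-like cells of smoking libraries had more RNA of Npm1 (ENSMUSG00000057113, mm10 chromosome 11, 33152287 to 33163206, minus strand, protein coding), which encodes nucleophosmin, a nucleolar protein of ribosome assembly. It rose from 1330 ± 75.2 to 1866 ± 155 CPM (SD, n = 3; edgeR log2 fold 0.49, SE 0.08, adjusted p = 0.00415) and was higher in 3 of 3 smoking libraries than in every control. Ptcra (chromosome 17, 46755663 to 46763712), the pre-T cell receptor alpha chain, rose from 18.8 ± 7.58 to 60.5 ± 41.3 CPM with overlap between the groups (log2 fold 1.82, SE 0.34, edgeR adjusted p = 0.0103). Pbld1 (chromosome 10, 63060162 to 63077962) fell from 54.0 ± 23.9 to 10.7 ± 10.9 CPM (log2 fold −2.12, SE 0.39, edgeR adjusted p = 0.0103). These calls rest on 172 UMIs for Ptcra and 141 for Pbld1 over all libraries. Without smoking library 2 the log2 fold was 1.15 for Ptcra in spermatogonia (edgeR adjusted p = 0.604) and −3.45 for Pbld1 in spermatogonia (0.00198). The next smallest p-values belonged to the axonemal dynein gene Dnah8 (log2 fold −1.11, SE 0.24) and the splicing factor gene Cwc22 (0.71, SE 0.15), both with an edgeR adjusted p of 0.0578. The groups overlapped for Dnah8, and free RNA was expected to give 68.4% of its UMIs.

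Lists of genes moved in these cells in opposite directions, in 8 calls that were all lost at adjusted p = 0.938 with an estimated correlation. All 22 measured genes of cholesterol biosynthesis had a positive fold (median log2 fold 0.30, camera adjusted p = 0.00024), among them Nsdhl at 0.81 (SE 0.34) and Srebf2, the transcription factor of the pathway, at 0.38 (SE 0.18). Of 20 stem cell and differentiation genes, 16 were positive (median 0.10, camera adjusted p = 0.0292), with Sohlh1 at 0.36 (SE 0.16) and Sall4 at 0.54 (SE 0.27), while Stra8, which is induced at meiotic entry, was at −0.20 (SE 0.14). The 13 mitochondrially encoded transcripts were all positive (median 0.13, camera adjusted p = 0.0453), as were 80 of 91 ribosomal protein genes (median 0.11, camera adjusted p = 0.000362). Genes of later germ cell stages fell as lists: 30 of 31 flagellum genes (median −0.33, camera adjusted p = 1.67e-07), 17 of 20 acrosome genes (−0.31, 7.96e-05), 17 of 19 chromatin condensation genes (−0.26, 0.000608) and all 15 abundant spermatid transcripts (−0.29, 5.11e-06) were negative. After subtraction of free RNA the mean log2 CPM difference turned from −0.34 to 0.23 for the acrosome list and from −0.32 to 0.25 for the spermatid transcripts. Adjusted over the list alone, 12 spermatid transcripts, 7 chromatin condensation genes and 3 flagellum genes were lower, 1 ribosomal protein gene was higher, and no gene of the other 4 lists passed. The expected free RNA made up 82.0% of the UMIs of the spermatid transcripts, 81.2% of the acrosome list, 73.4% of the flagellum list and 70.2% of the chromatin condensation list in these sums, but 7.96% for cholesterol biosynthesis and 2.18% for the stem cell list.

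In spermatogonia-like sums of 510566 to 905493 UMIs per library, edgeR called 2 genes higher and 1 lower of 8529, with 602 genes at an unadjusted p under 0.05. DESeq2 and limma-voom called 1 gene each. Cluster 32 held 46.0% of spermatogonia-like cells in controls and 29.0% in smoking libraries, and cluster 33 held 42.0% and 53.6%. Groups did not overlap for 12.2% of genes, where chance gives 10%. No gene was called after subtraction of free RNA, with Npm1 at a log2 fold of 0.43 and an edgeR adjusted p of 0.311. Without control 2 and without control 3 the adjusted p of Npm1 in spermatogonia-like cells was 0.0626 and 0.0795, and the number of calls was 31, 3 and 0 without controls 1, 2 and 3 and 12, 6 and 7 without smoking libraries 1, 2 and 3.

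Spermatocyte- and round-spermatid-like cells had higher RNA of genes for oxidative phosphorylation and ribosomes as groups, in calls that were all lost at adjusted p = 0.938 with an estimated correlation. In spermatocyte-like cells 52 of 56 nuclear oxidative phosphorylation genes (median log2 fold 0.10, camera adjusted p = 0.000211), with Sdhd of complex II at 0.33 (SE 0.12), and 87 of 92 ribosomal protein genes (0.11, 3.29e-06) were positive. In round-spermatid-like cells 44 of 56 oxidative phosphorylation genes (0.11, 0.00269), 81 of 94 ribosomal protein genes (0.13, 1.67e-07) and 24 of 31 ubiquitin-proteasome genes (0.10, 0.0268) were positive. Cluster 2 held 46.8% of round-spermatid-like cells in controls and 38.3% in smoking libraries, and cluster 19 gave 56.1% and 68.0% of their UMIs. The fold predicted from the cluster mix alone, with cluster profiles pooled over both groups, had the observed sign for 77.9% of all genes there. In stage-matched sums the 3 calls in round-spermatid-like cells were lost, at mean log2 CPM differences of −0.0027 (0.069 before matching) for oxidative phosphorylation, 0.0505 (0.13) for ribosomal protein and 0.0283 (0.0875) for ubiquitin-proteasome genes (camera adjusted p of 0.955, 0.182 and 0.610), while both calls in spermatocyte-like cells stayed past the threshold. The oxidative phosphorylation call in round-spermatid-like cells was also lost without smoking library 3 (0.0436, adjusted p = 0.0617), and the ubiquitin-proteasome call without control 1 (0.06, 0.0885), control 2 (0.0775, 0.120) or smoking library 3 (0.0573, 0.166). After subtraction of free RNA oxidative phosphorylation in spermatocyte-like cells did not pass (0.227).

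Other lists fell, in 4 calls that were also lost at adjusted p = 0.938 with an estimated correlation. In round-spermatid-like cells all 13 mitochondrially encoded transcripts were negative (median log2 fold −0.37, camera adjusted p = 0.000884), with mt-Nd2 at −0.60 (SE 0.13) and mt-Nd5 at −0.61 (SE 0.14), both subunits of complex I. Among 18 genes of the unfolded protein response 14 were negative (−0.19, 0.0404), and among 15 Sertoli function genes 13 (−0.50, 0.0214). In spermatocyte-like cells 12 of 15 abundant spermatid transcripts were negative (−0.49, camera adjusted p = 0.0161), with free RNA expected to give 65.3% of their UMIs. Adjusted over the list alone, 8 mitochondrial transcripts were lower in round-spermatid-like cells, and no gene of the other lists that passed in either class did so. Free RNA was expected to give 61.8% of the UMIs of the mitochondrial transcripts, and in stage-matched sums the list lay in the other direction, with a mean log2 CPM difference of 0.16 against −0.36, and it still passed the camera test there.

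No single gene passed in either class. Among genes with a mean of at least 10 CPM, the smallest p-values in round-spermatid-like cells belonged to the antisense gene Gm13307, at 149 ± 1.77 CPM in controls and 104 ± 1.65 in smoking libraries (log2 fold −0.53, edgeR adjusted p = 0.105), and to Npm1, at 263 ± 20.7 and 397 ± 37.1 CPM (0.59, adjusted p = 0.105). Below that mean, Fibcd1 (1.92) and Mup3 (−2.90) had the same adjusted p. The next from 10 CPM were 1700071G01Rik (1.24, 0.136), the lamin gene Lmnb2 (0.36, 0.339) and 4933406K04Rik (0.66, 0.339). In spermatocyte-like cells, again from a mean of 10 CPM, they belonged to the zinc finger gene Zfp820 (−1.62), the nuclear RNA Malat1 (−0.61), AY036118 (−0.71), Tes (−0.81, 96.6% free RNA) and Asb4 (0.93), all with an edgeR adjusted p of 0.364. Zfp820 is a leading gene of cluster 13, which held 33.4% ± 1.26 of spermatocyte-like cells in controls and 23.3% ± 1.19 in smoking libraries.

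In spermatocyte-like sums of 3433688 to 5776697 UMIs, edgeR called 0 of 11569 genes, with 1462 at an unadjusted p under 0.05, DESeq2 called 8 and limma-voom 0. Without control 3 edgeR called 354 genes, 333 of them lower, and in stage-matched sums 703, of which 593 were lower. In round-spermatid-like sums of 7033825 to 17960318 UMIs, it called 0 of 13936, with 1907 at an unadjusted p under 0.05, DESeq2 called 40 and limma-voom 0. Groups did not overlap for 16.2% of genes in spermatocyte-like and 19.2% in round-spermatid-like cells, where chance gives 10%.

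In elongating-spermatid-like cells of smoking libraries edgeR called 131 genes lower and 15 higher. The falls included Hemgn (ENSMUSG00000028332, chromosome 4, 46393989 to 46413506, minus strand, protein coding), from 281 ± 46.9 to 138 ± 12.3 CPM (SD, n = 3; log2 fold −1.02, SE 0.13, edgeR adjusted p = 0.00744), and Ropn1l (ENSMUSG00000022236, chromosome 15, 31441211 to 31453737), which encodes a protein of the sperm flagellum, from 1446 ± 222 to 884 ± 51.3 CPM (−0.71, SE 0.12, 0.023). Gtsf1, of the piRNA pathway that silences transposons, fell from 692 to 458 CPM (−0.59, SE 0.10, 0.023), Syce3, of the synaptonemal complex, from 366 to 263 CPM (−0.47, SE 0.10, 0.0384), and the ribosomal protein genes Rps14 and Rpl34 fell at log2 folds of −0.68 and −0.48 (0.0191 and 0.0465). Rises included Camk2b (ENSMUSG00000057897, chromosome 11, 5969644 to 6066362), a calcium and calmodulin-dependent kinase subunit, from 14.1 ± 3.11 to 32.3 ± 8.42 CPM (1.20, SE 0.20, 0.023).

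The largest other falls were those of Gm10827 (log2 fold −1.46), Gm8251 (−1.38), Gm13324 (−1.18), Dcdc2c (−1.14, chromosome 12, 28437795 to 28552399), Faiml (−1.14), Abra (−1.10), BC031181 (−1.08), Malat1 (−1.06, 92.8% free RNA) and Gm48051 (−1.0), with edgeR adjusted p from 0.00744 to 0.0422. Other rises that met the naming rule were those of the lincRNA 4933411E08Rik (1.09), Lyrm7 (0.88), Tmem239 (0.82), Gm47819 (0.66), Smim23 (0.55), Nsun7 (0.53) and Hoxa4 (0.50), with adjusted p from 0.0133 to 0.0498. Hemgn, Faiml and Dcdc2c are leading genes of cluster 24, and Gm48051 and Gm8251 are among those of other clusters. Cluster 24 held 16.7% ± 5.76 of elongating-spermatid-like cells in controls and 7.65% ± 1.79 in smoking libraries, while cluster 6, with Prm1 and Prm2 among its leading genes, held 49.9% ± 9.78 and 64.7% ± 3.83, and cluster 15 held 33.5% ± 4.24 and 27.6% ± 2.11.

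**Figure D2:**
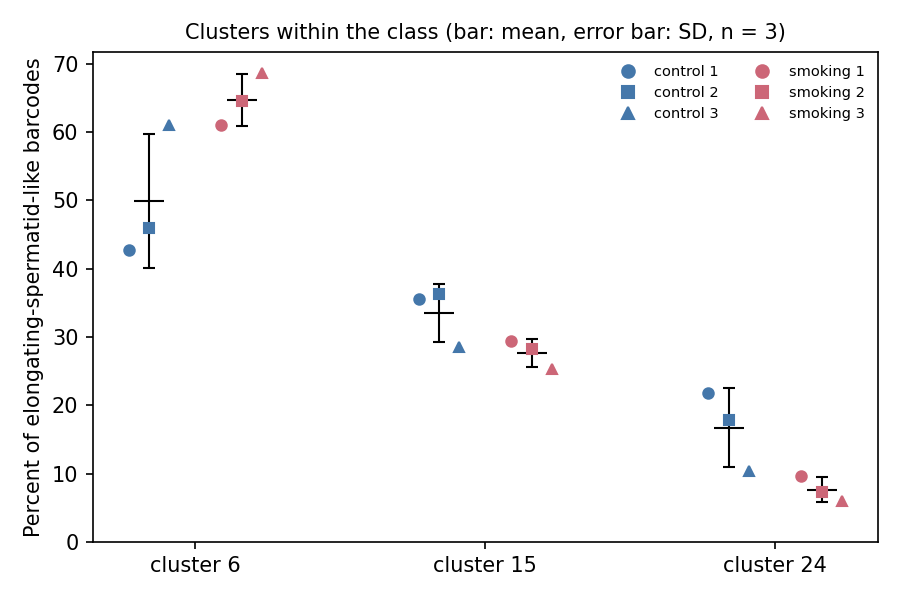
Percent of elongating-spermatid-like barcodes (y axis) in clusters 6, 15 and 24 for 3 control and 3 smoking libraries, with 1 point per library, a bar at the group mean and an error bar of 1 SD (n = 3). Cluster 24 lies at 21.8%, 17.9% and 10.4% in controls 1 to 3 and at 9.58%, 7.33% and 6.05% in smoking libraries 1 to 3.

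In elongating-spermatid-like cells 5 list calls were made, all lost at adjusted p = 0.938 with an estimated correlation. Of 15 abundant spermatid transcripts 14 were positive (median log2 fold 0.31, camera adjusted p = 0.000356), with the protamine genes Prm1 at 0.40 (SE 0.17) and Prm2 at 0.38 (SE 0.16). Prm1, Prm2, Smcp, Akap4 and Gapdhs were among the markers that named cluster 6. That cluster gave a mean of 39.8% of the UMIs of these cells in controls and 59.2% in smoking libraries. The list values in these sums therefore mix the cluster shares with any change inside the cells. Of 11 glutathione S-transferases, which conjugate electrophiles, 10 were positive (0.36, 0.00497), led by Gsta4 at 0.88 (SE 0.21, edgeR adjusted p = 0.0569). Of 22 glycolysis genes 16 were positive (0.28, 0.0373), with the sperm isoforms Pgk2 at 0.42 (SE 0.13) and Gapdhs at 0.35 (SE 0.13), and Ldha at −0.37 (SE 0.11). Of 90 ribosomal protein genes 68 were positive (0.23, 0.000218), against the falls of Rps14 and Rpl34, and of 30 meiotic recombination genes 20 were negative (−0.17, 0.0214). Adjusted over the list alone, 11 spermatid transcripts, 1 glutathione S-transferase, 7 glycolysis genes and 30 ribosomal protein genes were higher, and 2 glycolysis, 9 ribosomal protein and 2 meiotic recombination genes were lower. The lists of Gtsf1 (piRNA, 22 genes) and Ropn1l (flagellum, 38 genes) did not pass, at camera adjusted p of 0.311 and 0.474.

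In elongating-spermatid-like sums of 4333838 to 28922389 UMIs, edgeR called 146 of 11246 genes, with 2317 at an unadjusted p under 0.05. DESeq2 scaling and testing called 252 higher and 359 lower, limma-voom 6 and 80, and groups did not overlap for 25.9% of genes, where chance gives 10%. In stage-matched sums edgeR called 2 genes, 1 of them among the 146, and after subtraction of free RNA 8. The count was 9, 7 and 2213 without controls 1, 2 and 3, 0, 50 and 12 without smoking libraries 1, 2 and 3, and 6 without controls 1 and 2, the libraries with the fewest of these cells.

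The effect of smoke did not differ past the threshold between neighbouring germ cell classes. With limma 0 of 10951 genes passed for elongating- against round-spermatid-like cells, 0 of 10754 for round-spermatid- against spermatocyte-like cells and 0 of 7789 for spermatocyte- against spermatogonia-like cells. At an unadjusted p under 0.05 there were 1430, 1149 and 511 genes, and edgeR with a library block also called 0, with 1945, 1558 and 536 at an unadjusted p under 0.05.

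Macrophage-like cells of smoking libraries had more RNA of Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, plus strand, protein coding), a chemokine that attracts monocytes, which rose from 722 ± 463 to 2781 ± 1288 CPM (SD, n = 3; log2 fold 1.93, SE 0.29, edgeR adjusted p = 0.00125). The C-type lectin receptor gene Clec4n (ENSMUSG00000023349, chromosome 6, 123229843 to 123247021) rose from 242 ± 48.6 to 474 ± 57.4 CPM (0.95, SE 0.18, 0.0145), and Ms4a6c (ENSMUSG00000079419, chromosome 19, 11469366 to 11482192) from 215 ± 44.4 to 408 ± 45.1 CPM (0.92, SE 0.18, 0.0257). The prostaglandin D synthase gene Ptgds rose from 42.0 ± 10.4 to 270 ± 321 CPM (2.83, SE 0.54, 0.0145), and the fatty acid-binding protein gene Fabp5 from 11.0 ± 8.34 to 62.9 ± 14.7 CPM (2.33, SE 0.48, 0.0318). In control sums of 229092 to 334747 UMIs, 11.0 CPM is only a few UMIs per library. The lincRNA Gm48168 fell from 146 ± 20.5 to 48.9 ± 15.9 CPM (−1.65, SE 0.28, 0.00452), with 94.0% of its UMIs expected from free RNA. Ccl8 is among the leading genes of the macrophage-like cluster, and Ptgds is among those of the Leydig-like clusters. Smoking library 2 carried the rise of Ptgds in macrophages, at 640 CPM against 66.1 and 103 in smoking libraries 1 and 3, and without it the log2 fold was 1.04 (edgeR adjusted p = 0.230). The call was also lost without control 2 (0.184) and without control 3 (0.069).

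Inflammatory lists did not pass in these cells. Of 15 NF-kB and cytokine genes 10 were positive (camera adjusted p = 0.146), 2 of them higher when adjusted over the list alone, with Ccl7 at 1.00 (SE 0.23, edgeR adjusted p = 0.0943) and Il1b at −0.55. Of 7 interferon genes 6 were positive (0.155), 1 higher adjusted over the list alone, and of 14 antigen presentation genes 12 (0.165). Of lists, 7 passed, with all 7 calls lost at adjusted p = 0.938 with an estimated correlation. They were mitochondrially encoded transcripts, with 11 of 12 positive (median 0.20, camera adjusted p = 0.0338), and ubiquitin-proteasome genes, with 21 of 29 positive (0.18, 0.0434). Germ cell lists fell: 17 of 19 acrosome genes (−0.30, 0.000362), 24 of 29 flagellum genes (−0.24, 0.00111), all 10 meiotic recombination genes (−0.22, 0.0172), all 8 piRNA genes (−0.33, 0.0231) and all 15 spermatid transcripts (−0.19, 0.0453) were negative. The mean log2 CPM difference of the spermatid transcripts turned from −0.19 to 0.29 after subtraction of free RNA and 0.13 with doublets kept. Their call was also lost without control 1 (camera adjusted p = 0.0885), control 2 (0.364), smoking library 1 (0.272) or smoking library 3 (0.140). Adjusted over the list alone, 3 mitochondrial transcripts were higher and 1 flagellum gene lower. Free RNA was expected to give 87.0% to 91.4% of the UMIs of these germ cell lists.

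In macrophage-like sums of 229092 to 412345 UMIs, edgeR called 5 genes higher and 1 lower of 4640, with 383 at an unadjusted p under 0.05, limma-voom called 4 and DESeq2 0. No gene was called with doublets kept or with free RNA subtracted, where Ccl8 had a log2 fold of 1.8 and an edgeR adjusted p of 0.985. The count was 7, 2 and 6 without controls 1, 2 and 3 and 4, 20 and 6 without smoking libraries 1, 2 and 3, and groups did not overlap for 13.4% of genes, where chance gives 10%.

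**Figure D3:**
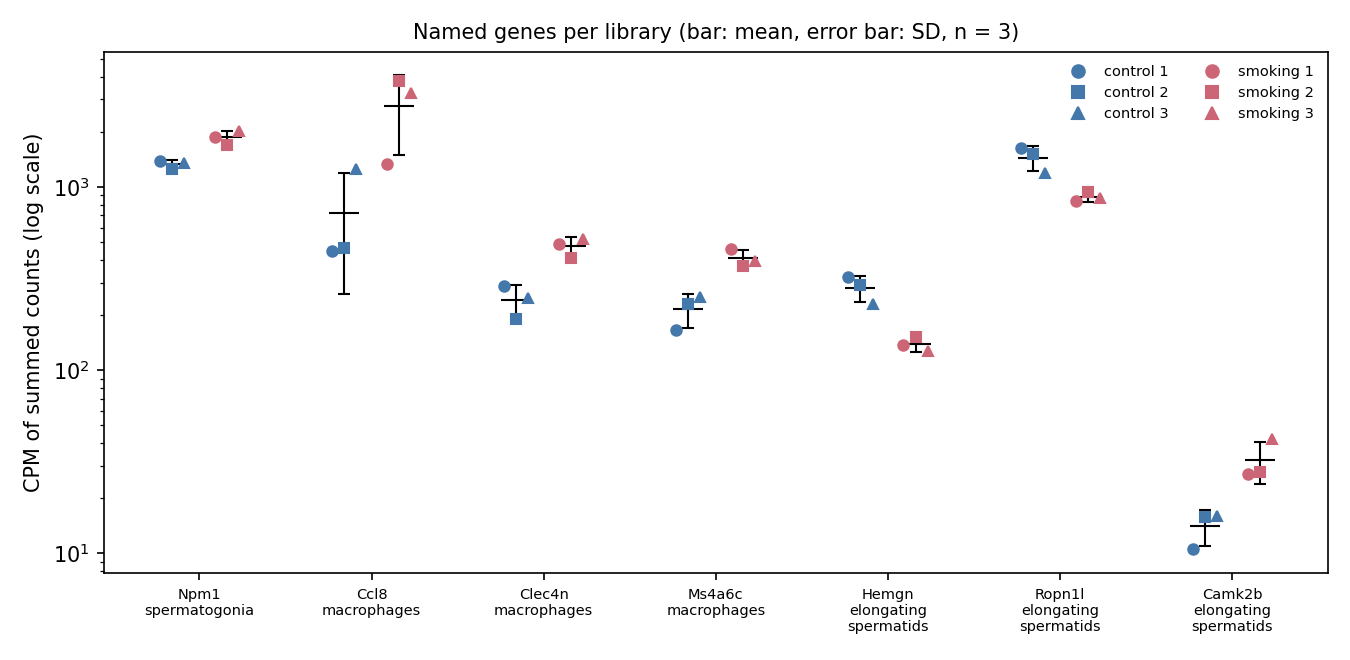
CPM of summed counts (y axis, log scale) of Npm1 in spermatogonia-like cells, Ccl8, Clec4n and Ms4a6c in macrophage-like cells, and Hemgn, Ropn1l and Camk2b in elongating-spermatid-like cells, with 1 point per library, a bar at the group mean and an error bar of 1 SD (n = 3). The 3 control and 3 smoking libraries do not overlap for any of these genes, and Ccl8 has mean values of 722 and 2781 CPM.

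Leydig-like cells of smoking libraries had lower RNA of steroid synthesis genes as a group. Of 23 steroidogenesis genes 20 were negative (median log2 fold −0.25, camera adjusted p = 0.00269), and of 22 cholesterol biosynthesis genes 18 (−0.28, 0.000218), both lost at adjusted p = 0.938 with an estimated correlation. Star, which moves cholesterol into mitochondria, was at 840 ± 145 CPM in controls and 457 ± 149 in smoking libraries (−0.88, SE 0.29), and Cyp17a1, which makes androgen precursors, at 9078 ± 952 and 6021 ± 2132 CPM (−0.59, SE 0.27). Values for Cyp11a1 (−0.39), Hsd17b3 (−0.34), Lhcgr (−0.27) and Hsd3b1 (−0.07) were negative, and the peptide hormone gene Insl3 was at 3663 ± 771 and 6363 ± 3160 CPM (0.80, SE 0.39). None of these 7 genes passed (edgeR adjusted p from 0.989 to 0.993). Smoking library 1 stood apart, with 86.5% of its Leydig-like cells in cluster 26, against 45.2% and 64.1% in smoking libraries 2 and 3 and 54.7% to 61.0% in controls. It had the lowest Star (285 CPM), Cyp17a1 (3630) and Cyp11a1 (1370). Without smoking library 1 the mean log2 CPM difference was 0.0071 for steroidogenesis (−0.23 with it) and −0.11 for cholesterol biosynthesis (−0.29 with it), and both calls were lost (camera adjusted p of 0.920 and 0.213). The steroidogenesis call was also lost in stage-matched sums (−0.11, 0.139), and that of cholesterol biosynthesis without control 1 (−0.19, 0.0789).

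Of 28 NRF2 and antioxidant genes 19 were negative in Leydig-like cells (−0.19, camera adjusted p = 0.0108), a call lost at adjusted p = 0.938 with an estimated correlation, as were the 3 others in these cells. Of 17 immediate early genes, which respond to tissue dissociation, 16 were positive (0.32, 0.0396), with Dusp1 at 0.46 and Junb at 0.43. All 20 acrosome genes (0.71, 0.0029) and 9 of 11 meiotic division genes (0.59, 0.0171) were positive, with 77.1% and 78.4% of their UMIs expected from free RNA against 0.293% for steroidogenesis. Without smoking library 1 the mean log2 CPM difference of the acrosome list turned from 0.45 to −0.15 (camera adjusted p = 0.257), and the NRF2 call was lost (0.587). Both calls were also lost in stage-matched sums (camera adjusted p of 0.273 for acrosome and 0.128 for NRF2) and after subtraction of free RNA (0.139 for each). The acrosome call was lost without control 1 as well (0.151), and the NRF2 call without control 3 (0.0768). Adjusted over the list alone no gene of the 6 lists passed. In Leydig-like sums of 316707 to 1111136 UMIs, edgeR, DESeq2 and limma-voom called 0 of 6507 genes, with 87 at an unadjusted p under 0.05 by edgeR, and edgeR called 7 without smoking library 1. The share of genes without overlap between the groups was 6.44%, where chance gives 10%. The smallest p-values belonged to Hook2 (1.21), Nprl2 (1.25), Pno1 (−1.14), Iqub (1.34, 100% free RNA) and Sc5d of cholesterol synthesis (−0.90), all with an edgeR adjusted p of 0.989.

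Sertoli-like cells, which nurse the germ cells, had 4 list calls, all lost at adjusted p = 0.938 with an estimated correlation. They had 14 of 18 glutathione S-transferases positive (median log2 fold 0.20, camera adjusted p = 0.0047), with Gsta4 at 0.29 (SE 0.12) and Gstp1 at 0.45 (SE 0.20), and 74 of 92 ribosomal protein genes positive (0.05, 0.0092). Of 24 meiotic recombination genes 19 were negative (−0.15, 0.0106) and of 18 chromatin condensation genes 16 (−0.12, 0.0466). No member passed adjusted over the list alone. Sertoli function genes, 16 of 21 positive (camera adjusted p = 0.102), and blood-testis barrier genes, 11 of 19 positive (0.785), did not pass. Free RNA was expected to give 54.2% to 68.6% of all UMIs in these sums. In sums of 1778224 to 4028721 UMIs edgeR called 0 of 10664 genes, with 324 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and edgeR called 7 without smoking library 3. The share of genes without overlap between the groups was 8.06%, where chance gives 10%. Among the smallest p-values from a mean of 10 CPM were those of Scgn (−2.17, adjusted p = 0.0518, 79.3% free RNA), Gm13307 (−0.69, 0.840, 83.0% free RNA), 4930557F10Rik (1.12, 0.853) and Defb45 (0.47, 0.999), a leading gene of Sertoli-like cluster 3.

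Mesenchymal-like cells had 11 of 12 mitochondrially encoded transcripts positive (median log2 fold 0.26, camera adjusted p = 0.0184). This call was lost at adjusted p = 0.938 with an estimated correlation, and no member passed adjusted over the list alone. The insulin-like growth factor-binding protein gene Igfbp3 was at 253 ± 38.4 CPM in controls and 52.1 ± 54.3 in smoking libraries (−2.13, SE 0.39, edgeR adjusted p = 0.0544), and the chemokine gene Cxcl1 had a log2 fold of −2.17 (SE 0.50, 0.416). Others were Dnah8 (−1.15, 0.416) and Gm48168 (−1.37, 0.416), with all UMIs of both expected from free RNA. In sums of 121852 to 260435 UMIs edgeR called 0 of 4028 genes, with 169 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and edgeR called 11 without control 2. The share of genes without overlap between the groups was 8.19%, where chance gives 10%.

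Genes that respond to smoke constituents did not pass in any class. The aryl hydrocarbon receptor, which binds polycyclic hydrocarbons of tar, induces Cyp1a1, for which 0, 0 and 1 UMIs were seen in controls and 1, 2 and 3 in smoking libraries. Ahrr had 49 UMIs in all, and neither gene was tested. Log2 folds were −0.23 for Cyp1b1 in mesenchymal-like cells (SE 0.42, edgeR adjusted p = 0.999), 0.08 for Tiparp in spermatogonia-like cells (0.953), −0.44 for Nqo1 in Leydig-like cells (0.989), 0.11 for the heme oxygenase gene Hmox1 in macrophage-like cells (0.924), 0.13 for Gclm in spermatogonia-like cells (0.883) and 0.12 for Srxn1 in elongating-spermatid-like cells (0.564). Aryl hydrocarbon receptor targets as a list had 1 of 11 genes positive in all cells (camera adjusted p = 0.25). The lists of NRF2 and antioxidant genes and of glutathione S-transferases passed camera in the classes given above, in calls lost with an estimated correlation.

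The sum of all retained cells gave 7 list calls, all lost at adjusted p = 0.938 with an estimated correlation. The mix of cells differed with them: elongating-spermatid-like cells gave 16.7%, 12.8% and 29.5% of these UMIs in controls 1 to 3 and 30.2%, 33.5% and 43.2% in smoking libraries 1 to 3. In this sum 14 of 15 spermatid transcripts (median log2 fold 0.40, camera adjusted p = 1.21e-06), 81 of 96 ribosomal protein genes (0.13, 1.67e-07) and 18 of 24 glycolysis genes (0.13, 0.0319) were positive. Negative were 33 of 40 meiotic recombination genes (−0.19, 0.00497), 20 of 24 piRNA genes (−0.11, 0.0171), 23 of 28 chromatin modifier genes (−0.18, 0.0172) and all 13 mitochondrial transcripts (−0.17, 0.0334). Adjusted over the list alone, 2 spermatid transcripts and 1 chromatin modifier gene were higher and 4 piRNA genes lower. In sums of 33780815 to 66886675 UMIs edgeR called 0 of 18914 genes, with 2900 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 557, of which 511 were higher, and groups did not overlap for 21.4% of genes, where chance gives 10%. Among genes with a mean of at least 10 CPM the smallest p-values belonged to Smim23 (0.69), 4933411E08Rik (1.15), Sfi1 (−0.77), BC049739 (0.50) and Tmem156 (0.60), all with an edgeR adjusted p of 0.264. Below that mean, Zfp820 (−1.51) had the lowest adjusted p of all genes, 0.177.

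Over all classes camera passed 47 of 253 list and class pairs, 24 of them higher. With an estimated correlation 0 pairs passed, at adjusted p = 0.938, and fry passed 0 for a shift in 1 direction (lowest adjusted p = 0.431) and 0 for change in either direction (0.0787). Lists that passed in no class were heat shock (lowest camera adjusted p = 0.390), p53 targets (0.146), apoptosis (0.391), ferroptosis (0.220), autophagy (0.267), blood-testis barrier (0.532), interferon (0.155), NF-kB (0.146), antigen presentation (0.0824) and aryl hydrocarbon receptor targets (0.25).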

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

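The settings with barcodes of at least 6000 UMIs, free RNA subtracted, stage matching together with this subtraction, named barcodes as the denominator, and controls 1 and 2 left out were chosen after the results were seen, as were stage matching and thinning for single genes and stage matching and free RNA subtraction for lists and for differences between classes. No paired analysis was possible because replicate numbers only follow the order of deposit. Among gene and list counts 131 alternative values stayed within 1.5 times the value reported and 84 did not. For passing lists 277 kept direction and call, 222 kept only direction and 7 turned direction. For named genes 1125 kept both, 288 lost the call, 81 gained it and 18 turned direction. Of shares, ratios and library measures 237 moved by less than the spread between libraries and 12 by more. The cause was not tested unless given. Upper-quartile scaling gave no such change in any gene count, and the stricter barcode filter removes no barcode. Differences between neighbouring classes stayed at 0 genes under every setting run. In simulated counts edgeR recovered 6.56% of 2-fold changes in Leydig-, 50.8% in mesenchymal-, 63.5% in macrophage- and 64.6% in spermatogonia-like sums, against 55.2% to 72.7% in the others, and depth limited the genes tested to 4028 in mesenchymal- and 4640 in macrophage-like sums.

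With DESeq2 the number of genes called was 1 in spermatogonia-, 8 in spermatocyte-, 40 in round-spermatid-, 611 in elongating-spermatid-, 1 in Sertoli-, 0 in macrophage- and 1 in mesenchymal-like cells and 557 in all cells. Limma-voom gave 1 in spermatogonia- and 86 in elongating-spermatid-like cells. Without the filter on low counts edgeR called 27 in spermatogonia-, 485 in spermatocyte-, 366 in round-spermatid-, 953 in elongating-spermatid-, 33 in Sertoli-, 9 in Leydig-, 23 in macrophage- and 30 in mesenchymal-like cells and 1 in all cells. Thinning gave 2 in macrophage- and 1 in mesenchymal-like cells. With no filter on barcodes it called 6 in spermatogonia- and 1 in Sertoli-like cells, and with doublets kept 8 in spermatogonia-, 2 in spermatocyte-, 27 in elongating-spermatid-, 0 in macrophage- and 1 in mesenchymal-like cells. Leiden resolution 2 gave 0 in spermatogonia- and 1 in Sertoli-like cells, and resolution 0.5 gave 1 in Sertoli-like cells.

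Stage-matched sums gave 6 genes in spermatogonia-, 703 in spermatocyte-, 1 in round-spermatid-, 2 in elongating-spermatid- and 2 in Sertoli-like cells. After free RNA was subtracted edgeR called 0 in spermatogonia-, 2 in round-spermatid-, 8 in elongating-spermatid- and 0 in macrophage-like cells, and after both steps 0, 1, 0 and 0. Barcodes of at least 6000 UMIs gave 1 in round-spermatid- and 0 in macrophage-like cells. Without controls 1 and 2 it called 1 in spermatocyte-, 6 in elongating-spermatid-, 11 in macrophage- and 6 in mesenchymal-like cells and 3 in all cells. Of the 33 named calls, edgeR still called 10 in stage-matched sums, 5 of 32 after free RNA was subtracted and 0 of 32 after both, with none reversed. The 10 were 3 of 3 in spermatogonia-, 1 of 24 in elongating-spermatid- and 6 of 6 in macrophage-like cells. Macrophage-like cells formed 1 cluster, so stage matching could not change their sums. Of the 33, edgeR still called 12, 6 and 28 without controls 1, 2 and 3 and 6, 18 and 11 without smoking libraries 1, 2 and 3. The edgeR adjusted p of Ccl8 in macrophages was 0.0679 without control 2 and 0.119 with doublets kept, and its DESeq2 adjusted p was 0.999. For Clec4n in macrophages the edgeR adjusted p was over 0.05 without controls 2 and 3 and without smoking libraries 1 and 3.

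Leaving out each library in turn moved the number of genes called from 0 (without control 3) to 31 (without control 1) in spermatogonia-, from 0 to 354 (without control 3) in spermatocyte-, from 0 to 8 (without control 3) in round-spermatid-, from 0 (without smoking library 1) to 2213 (without control 3) in elongating-spermatid-, from 0 to 7 (without smoking library 3) in Sertoli-, from 0 to 7 (without smoking library 1) in Leydig-, from 2 (without control 2) to 20 (without smoking library 2) in macrophage- and from 0 to 11 (without control 2) in mesenchymal-like cells, and from 0 to 8 (without smoking library 3) in all cells. Other libraries that moved a count by over 1.5 times were smoking libraries 1, 2 and 3 in spermatogonia-like cells (12, 6 and 7 genes), smoking library 3 in spermatocyte-like cells (4), controls 1 and 2 and smoking libraries 1 and 3 in round-spermatid-like cells (1, 2, 1 and 7), controls 1 and 2 and smoking libraries 2 and 3 in elongating-spermatid-like cells (9, 7, 50 and 12), control 1 in Sertoli-like cells (1), control 1 and smoking library 1 in mesenchymal-like cells (2 and 3) and control 2 in all cells (1).

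Of the list and class pairs, 0 passed by camera with an estimated correlation, 0 by fry for 1 direction and 0 by fry for either direction, and 30 by camera after free RNA was subtracted, with 24 (without control 1) to 61 (without smoking library 2) on leaving out a library. Mean log2 CPM differences over a list turned for acrosome genes in spermatogonia-like cells (0.23 after free RNA was subtracted), for spermatid transcripts in spermatogonia-like cells (0.25 after the same) and in macrophage-like cells (0.29 after the same and 0.13 with doublets kept), and for mitochondrial transcripts in round-spermatid-like cells (0.16 in stage-matched sums). On leaving out a library they ranged from −0.20 to −0.0145 for chromatin condensation genes in Sertoli-like cells, where the test turned direction without smoking library 3, and from −0.15 (without smoking library 1) to 0.68 for acrosome genes in Leydig-like cells.

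None of the genes that turned sign was called. Log2 folds of Hmox1 in macrophages were −0.0557 for barcodes of at least 6000 UMIs, −0.0792 after free RNA was subtracted, −0.0792 after both steps and −0.0227 without controls 1 and 2. Hsd3b1 in Leydig-like cells was at 0.0253 with doublets kept, 0.0652 in stage-matched sums, 0.0093 for barcodes of at least 6000 UMIs, 0.0559 after both steps and 0.39 without controls 1 and 2. Tiparp in spermatogonia-like cells was at −0.00082 after free RNA was subtracted, and Srxn1 in elongating spermatids at −0.0344 without controls 1 and 2. On leaving out a library the range was −0.50 to 0.23 (without control 1) for Cyp1b1, −0.0487 (without smoking library 2) to 0.16 for Tiparp, −0.0637 (without smoking library 1; −0.0014 without control 2) to 0.22 for Hmox1, −0.27 to 0.14 (without smoking library 1, and 0.11 without control 1) for Hsd3b1 and −0.47 to 0.0197 (without smoking library 1) for Lhcgr.

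Log2 ratios of smoking to control shares are those of the X-like classes. For barcodes of at least 6000 UMIs the share of spermatogonia (log2 ratio) was −1.19 (exact p = 0.2), the share of spermatocytes (log2 ratio) −0.70 (0.1), the share of Sertoli (log2 ratio) −0.74 (0.1), the share of Leydig (log2 ratio) −0.27 (0.6), the share of mesenchymal (log2 ratio) −1.04 (0.3), the share of peritubular myoid (log2 ratio) −0.69 (0.3) and the share of unnamed (log2 ratio) −0.85 (0.2), and the log2 ratio of round-spermatid- to spermatocyte-like cells differed by 0.64 (0.1). Over named barcodes alone the share of spermatogonia was at −0.81 (exact p = 0.1), that of spermatocytes at −0.51 (0.2) and the share of round spermatids (log2 ratio) at −0.25 (0.1), and over germ cells alone that of spermatocytes was at −0.43 (0.3).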

Other observations

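All tests of explanations below were chosen after the result was seen, except the test of the cluster mix over all 146 genes called in elongating-spermatid-like cells and the count of list and class pairs over other splits of the libraries.

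Both of the genes Npm1 and Gm13307 had values in the same direction in most classes, and these were picked out after their values were seen. Npm1 was higher without overlap between the groups in spermatocyte- (log2 fold 0.41), Sertoli- (0.49), Leydig- (0.43) and mesenchymal-like cells (0.13) besides spermatogonia- and round-spermatid-like cells, and overlapped in elongating-spermatid- (0.20) and macrophage-like cells (0.10). The antisense gene Gm13307 was lower without overlap in spermatogonia- (−1.31), spermatocyte- (−0.64), elongating-spermatid- (−0.41) and mesenchymal-like cells (−0.88) besides round-spermatid- and Sertoli-like cells, overlapped in macrophage-like cells (−0.95), and lay in the other direction with overlap in Leydig-like cells (0.34). Free RNA was expected to give 83.0% to 94.6% of the UMIs of Gm13307 in spermatogonia-, Sertoli-, macrophage- and mesenchymal-like cells and 74.5% in Leydig-like cells. In spermatocyte-, round-spermatid- and elongating-spermatid-like cells it was 35.0%, 14.5% and 9.75%. For Npm1 it was 2.93% in spermatogonia-like and 55.4% in Sertoli-like cells. Since classes of a library share its free RNA and its mice, the folds of these genes are not independent between classes.

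The 131 genes lower in elongating-spermatid-like cells and the 15 higher behaved differently when the mix of clusters was taken into account. The fold predicted from the cluster mix alone had the observed sign for 100% of the genes called lower (131 of 131, exact 95% interval from 97.2% to 100%). The share was 95.89% of all called genes and 66.97% of all genes tested in the class. For the genes called lower the median ratio of predicted to observed fold was 1.041. Stage-matched sums still kept a median of 0.384 of their fold, with the median log2 fold going from −0.77 to −0.30. The cluster profiles pooled both groups, so a change inside the cells could add to the prediction. For the genes called higher the predicted fold had the observed sign in 60% (9 of 15, from 32.3% to 83.7%), and their median went from 1.00 to 0.84. Their median ratio of predicted to observed fold was 0.0388, which argues against the mix of clusters 6, 15 and 24 as their cause. A shift of spermatid steps inside a cluster was not tested, and both intervals treat genes of the same libraries as independent. Subtracting free RNA left folds at a median ratio of 1.14, which argues against free RNA as the cause of the median fold of the called genes. It does not cover single genes, such as Malat1 with 92.8% free RNA. After the subtraction 5 of 24 named calls in these cells were kept. Thinning to the UMI total of the shallowest sum left them at 1.022, but thinning keeps the expected CPM of each gene and matched neither the number of cells (207 to 1272 per library) nor the UMIs per cell (medians of 16634 to 24692), so deeper smoking libraries and a change in the cells cannot be told apart. A candidate explanation for part of the fall of the lower genes is a smaller share of cluster 24 among these cells in the smoking libraries. Whether smoke exposure or the sampling of cells from each testis set that mix stays open, as does a change inside the cells.

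Abundant spermatid transcripts were lower in spermatogonia- and spermatocyte-like cells, which may come from a smaller part of these sums being free RNA in smoking libraries. Their observed log2 fold minus that expected from free RNA alone had a median of 0.1267 in spermatogonia-like cells (observed −0.30, expected −0.42) and 0.08494 in spermatocyte-like cells (−0.49 and −0.57), leaving out the genes that set the free RNA level. In macrophage-like cells it was 0.09739, but these cells helped to set that level, so free RNA and a change in the cells cannot be told apart there. Over the 11 genes compared, free RNA was expected to give 79.4% of UMIs in spermatogonia-like but 37.9% in spermatocyte-like cells. The share of the median gene was 80.3% and 78.3%. In spermatocyte-like cells the fold expected from free RNA alone thus concerns only part of these UMIs. A biological change of these transcripts in spermatogonia- and spermatocyte-like cells was not tested.

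The fold of Npm1 in spermatogonia-like cells was positive and past the threshold in smoking libraries. Its log2 fold was 0.4293 after free RNA was subtracted and 0.4245 in stage-matched sums, against 0.49 as measured, which argue against free RNA and against the mix of clusters as the whole cause. After the subtraction the call ended at an edgeR adjusted p of 0.311 because the unadjusted p rose from 4.86e-07 to 8.2e-05, with a fold within 1 SE (0.08) of the measured one. As a hypothesis, nucleophosmin RNA may be higher in spermatogonia after smoke exposure, but differences between single mice stay open because the labels do not tie libraries to mice.

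In round-spermatid-like cells 27 genes had an 8-fold or larger range between libraries, 26 of them within 1 group, and the groups did not overlap for 14.81% of them, where chance gives 10%.

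With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As real value and highest of the other splits, the number of genes called was 146 and 5 in elongating-spermatid-like cells (1 split with at least as many), 3 and 17 in spermatogonia-like cells (3 splits) and 6 and 17 in macrophage-like cells (2 splits). It was 0 and 3 in spermatocyte- and Sertoli-like cells and in all cells, 0 and 2 in round-spermatid- and mesenchymal-like cells, and 0 and 0 in Leydig-like cells and for the 3 differences between neighbouring classes, with all 10 splits at least as large in each. The number of list and class pairs was 47 and 63 (4 splits).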
